A study of Mus musculus with 4 samples.

How the data were processed

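Polyadenylated RNA was measured by sequencing in 4 libraries of mouse epiblast stem cells of the line OE7. Per the labels' protocols, cells at passages 21 to 25 were grown on fibronectin. The medium held Activin A at 20 ng/ml, and Fgf2 was added at 12 ng/ml. Transfection in 6-well plates used 1000 ng of esiRNA and 2 µl of lipofectamine. Per the labels, poly(A) RNA was selected on oligo(dT) beads. The groups, taken from the library titles, were Luc esiRNA, the control (n = 2), and Tox4 esiRNA (n = 2).

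The authors deposited FPKM values, that is, fragments scaled to gene length and sequencing depth, for 15429 genes with Ensembl identifiers and symbols, 1 file per library and 1 table of the series that held identical values. The submitters' processing notes name CASAVA 1.8, the aligner STAR 2.3.0e and the genome build GRCm38.p1. The counting program, the gene annotation, the treatment of reads with several matches and the use of strand are not given in the sources used here. Reads from overlapping genes on opposite strands, and from close paralogs, could therefore have been assigned to either gene. Gene coordinates, types, exon lengths and GC content came from the GENCODE annotation of GRCm38, in which 15223 of the identifiers (98.7%) were found. The values of 57 symbols stand for more than 1 identifier each.

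FPKM values are not counts, but the depth could be worked back. Within each gene the values of the 4 libraries, after multiplication by a common depth per library, were whole multiples of the value of 1 read for 100% of values, to a relative tolerance of 2e-13. The smallest multiple that gave a whole gene length within 0.02 bp was taken as reads. For 4.35% of tested genes a common factor had to be chosen in this way. The totals were 19008811 and 14998197 reads in Luc replicates 1 and 2 and 14739230 and 12778047 in Tox4 replicates 1 and 2, which was 97.7% of the depth that the authors' scaling implies in each library. Recovery up to a common factor per gene was tested on simulated data. In 20 simulated tables with the genes and depths of this table, 100% of genes were returned each time. In 20 tables of 3000 genes with more uneven depths, the depth steps came out right in only 11, and as few as 0.837% of genes were returned. In the tables with wrong steps at most 13.7% of reads were odd numbers in the library with the lowest share, against 52.7% in the real table. The reads of replicates differed by more than sampling noise, with a chi-square per degree of freedom of 1.62 between the Luc libraries and 1.92 between the Tox4 libraries, so that no library was counted as a copy of another.

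Expression was tested on log2(FPKM + 1) for genes with a mean of at least 1 FPKM over the 4 libraries, with the moderated test of limma 3.58.1 in R 4.3.3, two-sided, with an intensity trend in the prior variance and Benjamini-Hochberg adjustment over the 12403 genes tested at a threshold of 0.05. All 4 libraries entered the fit, which had 2 residual and 4.01 prior degrees of freedom, with no covariate. A fold change is on the log2(FPKM + 1) scale and understates the change of genes with low values. On simulated reads for these 12403 genes with 200 changed genes, made 5 times, the fit recovered 37.3% of changes of 1.3-fold, 62.1% of 1.5-fold and 85.5% of 2-fold, and 7.81% of the genes called were false, above the nominal level. A simulated list of 16 genes shifted by 0.3 had an unadjusted camera p under 0.05 in 5 of 5 simulations, and an unchanged list in 1 of 5. The lists of the data were adjusted over 24 lists, so these rates do not carry over to them.

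A total of 26 gene lists of 3 to 20 genes were drawn up before the data were examined, as were the test, the filter, the pseudocount, the rule for naming genes and the first set of alternatives. The lists covered core, primed and naive pluripotency, the Nodal, FGF and Wnt pathways, germ layers and extraembryonic lineages, fibroblast markers, partners and relatives of Tox4, p53, interferon and stress responses, the cell cycle, metabolism, mitochondrial transcripts, ribosomal proteins, histones, immediate early genes and Hox genes. A list was tested with camera at a preset correlation of 0.01 when at least 3 members were tested, which held for 24 lists, with adjustment over those lists. Camera with an estimated correlation and fry were run beside it. With an estimated correlation camera refers a list to the 2 residual degrees of freedom, so that few lists can pass after adjustment. Older symbols were matched through synonyms. Genes were named by rule: Tox4 and Pou5f1; the 15 largest rises and 15 largest falls among genes past the threshold whose groups did not overlap and whose higher group mean was at least 5 FPKM, symbols of the Gm, LOC, Rik, AI, AW, BC, AU, -ps and -rs forms passed over; up to 4 members past the threshold of each list, or 2 where none passed; and any member of the core pluripotency list.

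The alternatives set in advance were pseudocounts of 0.1 and 0.5, no filter, a filter at a mean of 5 FPKM, median-of-ratios scaling, quantile normalization, no intensity trend, the replicate number as a block, each library left out in turn, an estimated correlation for the lists and a minimum fold of 1.5. After the data had been seen, limma-voom on the recovered reads, reads thinned to the depth of the shallowest library, a correction for GC content and gene length, and fits without overlapping genes or without short non-coding genes were added. Data handling used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.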

Results

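Polyadenylated RNA was sequenced from mouse epiblast stem cells, pluripotent cells taken from the post-implantation embryo, in which the chromatin-associated HMG-box protein gene Tox4 had been knocked down. The line, OE7, carries a green fluorescent reporter of Oct4, the protein of Pou5f1. The cells were grown with Activin A and Fgf2 and transfected with esiRNA, a pool of short interfering RNAs made by enzymatic digestion of long double-stranded RNA. There were 2 libraries of cells given Luc esiRNA, the control, and 2 of cells given Tox4 esiRNA. The table held FPKM values of 15429 genes, of which 303 were listed at 0 in all 4 libraries and 12403 had a mean of at least 1 FPKM and were tested. Whole reads worked back from the FPKM values came to 19008811 and 14998197 for Luc replicates 1 and 2, and to 14739230 and 12778047 for Tox4 replicates 1 and 2. Taken over all tested genes and the 4 libraries, the median was 548 reads per gene in a library. Mitochondrial genes took 0.864% and 0.840% of the reads in the Luc libraries and 1.05% in each Tox4 library, and the 10 most abundant genes took 4.88% to 5.002%. The labels do not say whether the libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

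The series addressed the regulation of Oct4 in pluripotent cells, and the comparison of Tox4 esiRNA with Luc esiRNA asked which transcripts differed after knockdown of Tox4. Tox4 itself (ENSMUSG00000016831) fell from 17.1 ± 0.573 FPKM in the Luc libraries to 8.77 ± 0.172 FPKM in the Tox4 libraries (SD, n = 2 each), a ratio of 0.512. Its values were 16.7 and 17.5 FPKM in Luc replicates 1 and 2 and 8.65 and 8.89 FPKM in Tox4 replicates 1 and 2, on 1697, 1404, 680 and 606 reads. The log2 fold change was -0.89 (SE 0.05, limma adjusted p = 0.00228). Tox4 lies on the plus strand of chromosome 14 from 52279146 to 52296401 (GRCm38), and 1128 bases of its exons overlap exons of Mettl3 and Rab2b on the opposite strand, whose reads cannot be separated from its own if strand was not used in counting.

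Pou5f1 (ENSMUSG00000024406, chromosome 17, 35506018 to 35510772, plus strand), which encodes Oct4, was at 585 ± 4.31 FPKM with Luc esiRNA and 598 ± 21.2 FPKM with Tox4 esiRNA (SD, n = 2 each). The log2 fold change was 0.03 (SE 0.04, 95% interval -0.07 to 0.13, limma adjusted p = 0.717), and it was -0.01 without Tox4 replicate 2. The difference was smaller than the spread between the Tox4 libraries, which held 583 and 613 FPKM.

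**Figure D1:**
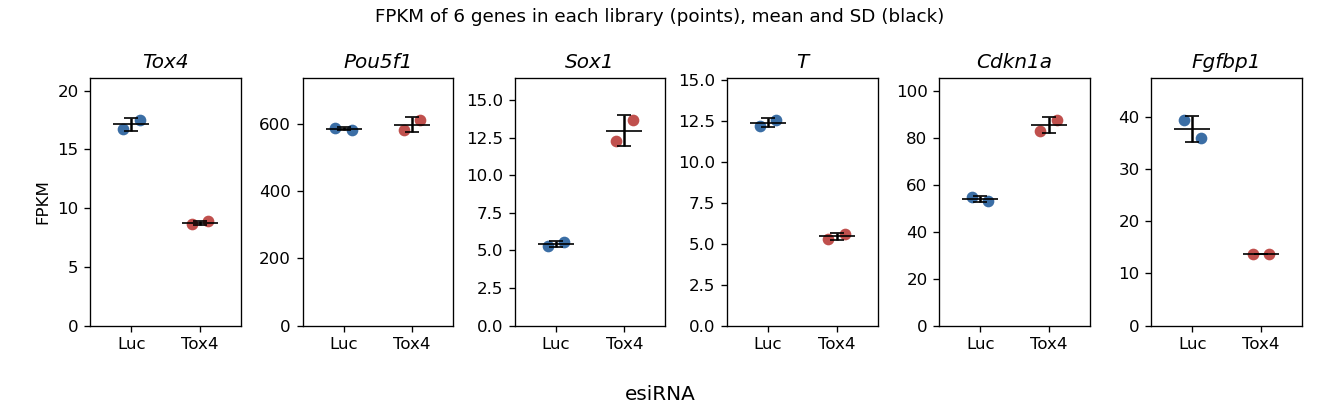
FPKM (vertical axes, each from 0) of Tox4, Pou5f1, Sox1, T, Cdkn1a and Fgfbp1 in the Luc esiRNA libraries (blue points) and the Tox4 esiRNA libraries (red points), with the mean and SD of the 2 libraries of each group in black. Both Tox4 libraries lie below both Luc libraries for Tox4, T and Fgfbp1 and above them for Sox1 and Cdkn1a, while for Pou5f1 the values of the groups overlap.

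Knockdown of Tox4 was accompanied by higher levels of 234 genes and lower levels of 325 genes (limma, adjusted p under 0.05 over 12403 genes). Most changes were modest: the median size among the 559 genes was 0.36 on the log2(FPKM + 1) scale, which understates the change of genes with low values. A rise of at least 1.5-fold was found for 43 genes and a fall of that size for 62, and at least 2-fold for 8 and 17. In 52.0% of the tested genes the values of the groups did not overlap, against 33.3% by chance. The counts fell when any 1 library was left out, most when it was a Luc library. Such a fit takes its spread from the 2 libraries of the other group alone. The fall therefore does not show whether the differences rested on 1 library. The counts also rested on the variance model, with 33 higher and 45 lower when no intensity trend was fitted and 738 and 728 in limma-voom on the recovered reads.

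**Figure D2:**
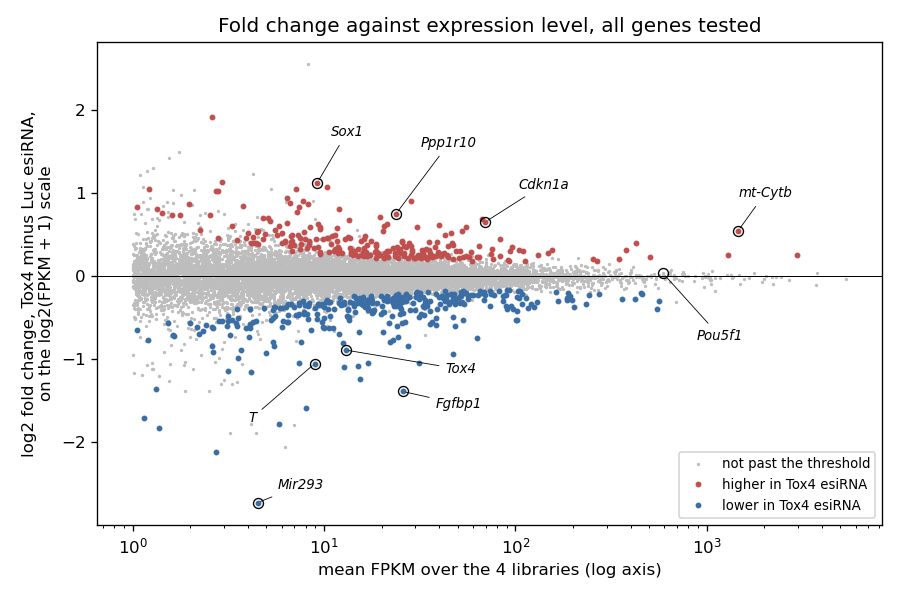
Log2 fold change of Tox4 esiRNA minus Luc esiRNA on the log2(FPKM + 1) scale (vertical axis) against the mean FPKM over the 4 libraries (horizontal log axis) for the 12403 genes tested, with the 234 higher genes in red, the 325 lower genes in blue, the others in grey and 9 named genes ringed. Among abundant genes mt-Cytb rose (0.54) and Pou5f1 lay near 0 (0.03).

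Among the genes named by rule, Sox1 and Svop had the largest rises on the log2(FPKM + 1) scale. Sox1 (chromosome 8, 12395295 to 12400126), a transcription factor of neural progenitors, rose from 5.43 ± 0.204 to 13.0 ± 1.03 FPKM, with a log2 fold change of 1.12 (SE 0.07, limma adjusted p = 0.00263). Svop, which encodes a synaptic vesicle protein, rose by 1.07 on the log2 scale, and Vgf, a neuropeptide precursor, by 1.05. Sez6 rose by 0.90, the growth factor gene Ptn by 0.90, Cbln1 by 0.88 and Fabp7, the brain fatty acid-binding protein, by 0.83. Ppp1r10, which encodes the PNUTS scaffold of the phosphatase complex that also contains Tox4, rose from 17.5 ± 0.532 to 30.0 ± 0.296 FPKM (log2 fold change 0.75, SE 0.04, adjusted p = 0.00228). The remaining genes with the largest rises were AC158662.1 (0.94), Col2a1 (0.84), Efnb1 (0.76), Rprm (0.71), Lrrn2 (0.69), Dnaic1 (0.69) and Dcxr (0.69). AC158662.1 is an RNA antisense to Pcbp1, and exons of Svop and Dnaic1 overlap those of Usp30 and Enho on the opposite strand. The rises of Cbln1, Col2a1, Lrrn2 and Dnaic1 were no longer past the threshold without Luc replicate 1 or without Luc replicate 2 (adjusted p up to 0.0742, 0.0751, 0.118 and 0.123), nor was that of Efnb1 without Luc replicate 2 (0.0580), whereas the other 10 stayed past it with each library left out in turn.

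The genes that fell most included Fgfbp1, Sfn and T. Fgfbp1 (chromosome 5, 43978858 to 43981779), whose protein releases Fgf from the matrix, fell from 37.7 ± 2.55 to 13.7 ± 0.0666 FPKM, with a log2 fold change of -1.39 (SE 0.06, limma adjusted p = 0.00170). T (chromosome 17, 8434423 to 8442496), the Brachyury gene of the primitive streak, fell from 12.4 ± 0.274 to 5.45 ± 0.202 FPKM (-1.06, SE 0.06, adjusted p = 0.00228). Sfn, which encodes the 14-3-3 sigma protein of epithelia, fell by 1.24 on the log2 scale, Fabp3 by 1.10, Gadd45b by 1.05, the adaptor gene Dok2 by 1.04, Ier3 by 0.93 and the membrane peptidase gene Mme by 0.89. The guanylate-binding protein genes Gbp2b and Gbp2 fell by 1.09 and 1.05, with the reservation that they are close paralogs between which reads could have been split, and the chemokine gene Cxcl11 fell by 0.99 on 29, 26, 9 and 9 reads. The microRNA genes Mir293, Mir295 and Mir291b on chromosome 7 had log2 fold changes of -2.73, -1.78 and -1.59. These rested on few reads (10, 13, 0 and 1 for Mir293) over genes that lie inside exons of Nlrp12 on the opposite strand. Mature microRNAs were not measured, since polyadenylated RNA was sequenced. A gene listed as Atf7 (ENSMUSG00000071584), an identifier that shares its symbol with another in the table, was at -0.93. Without Luc replicate 1 and without Luc replicate 2, Mir293, Cxcl11 and Mme were no longer past the threshold (adjusted p up to 0.0862, 0.0751 and 0.0691). Mir291b was lost without Luc replicate 1 (0.0517), Fabp3 without Luc replicate 2 (0.0726), and Atf7 without Luc replicate 1 or either Tox4 library (0.0991, 0.0625 and 0.0653).

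Most tested genes of the pluripotency lists did not pass the threshold. Of 12 tested members of the core pluripotency list, Sox2 rose (76.3 to 90.4 FPKM, log2 fold change 0.24), Tdgf1, a Nodal co-receptor gene, fell (397 to 326 FPKM, -0.28), and 10 did not pass, with the same counts of 1 and 1 adjusted over the list alone (camera adjusted p = 0.584). Nanog was at 199 and 198 FPKM (-0.0043), Lin28a at -0.09 and Utf1 at -0.13 on the log2 scale. Among 15 genes of primed, epiblast-type pluripotency, Epha4 (0.39) and Sall2 (0.25) rose and Cldn6, a tight junction gene, fell (-0.60), while 12 did not pass; adjusted over the list alone, 4 rose and 2 fell (camera adjusted p = 0.597). Among 7 tested genes of naive pluripotency, Gbx2 rose (0.52) and 6 did not pass; adjusted over the list alone, 1 rose and 1 fell (camera adjusted p = 0.355). Cldn6 kept its call with each library left out, whereas Sox2, Tdgf1, Epha4, Sall2 and Gbx2 lost theirs with either Luc library left out (adjusted p up to 0.179, 0.141, 0.179, 0.228 and 0.0957), as did Epha4 and Sall2 with either Tox4 library left out and Sox2 without Tox4 replicate 1.

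Listed genes of the Nodal, FGF and Wnt pathways showed few calls in either direction. Of 14 genes of the Nodal and Activin pathway, Cer1 (0.35) and Smad7 (0.26) rose, none fell and 12 did not pass; adjusted over the list alone, 4 rose and 1 fell (camera adjusted p = 0.104). Of 16 FGF and ERK targets, Spry2, a feedback inhibitor, rose (0.25), Ier3 (-0.93) and Etv5 (-0.26) fell and 13 did not pass; adjusted over the list alone, 5 rose and 2 fell (camera adjusted p = 0.137). Of 8 Wnt and beta-catenin targets, the cyclin genes Ccnd2 (0.24) and Ccnd1 (0.22) rose and 6 did not pass, with 2 rising when adjusted over the list alone (camera adjusted p = 0.107). Ier3 kept its call with each library left out. Cer1, Smad7, Spry2, Etv5, Ccnd2 and Ccnd1 lost theirs with either Luc library left out (adjusted p up to 0.197, 0.192, 0.157, 0.223, 0.179 and 0.236), as did Cer1, Smad7, Spry2 and Ccnd1 with either Tox4 library left out, Ccnd2 without Tox4 replicate 1 and Etv5 without Tox4 replicate 2.

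Lineage markers moved in different directions, with neuroectoderm genes higher and trophoblast and extraembryonic endoderm genes lower. Of 7 tested neuroectoderm genes, Sox1 (1.12), Fabp7 (0.83) and Ncam1 (0.34) rose and 4 did not pass, with 3 also adjusted over the list alone (median 0.13). The list passed with a preset correlation (camera adjusted p = 0.00330, adjusted p = 0.368 with an estimated correlation). Of 11 trophoblast and extraembryonic endoderm genes, Krt18 (-0.46), Sparc (-0.34) and Krt8 (-0.30) fell and 8 did not pass, with 3 also adjusted over the list alone (median -0.15, camera adjusted p = 0.00268, adjusted p = 0.368 with an estimated correlation). These encode simple-epithelial keratins and a matrix protein. Of 11 primitive streak and mesendoderm genes, T fell (-1.06) and 10 did not pass; adjusted over the list alone, 1 rose and 2 fell (camera adjusted p = 0.201). Of 8 definitive endoderm genes, the epithelial genes Krt19 (-0.74) and Epcam (-0.31) fell, Cer1 rose (0.35) and 5 did not pass; adjusted over the list alone, 4 fell and 2 rose (camera adjusted p = 0.206). Of 5 mesoderm and epithelial-mesenchymal transition genes, Bmp4 fell (-0.40) and 4 did not pass, with 2 falling when adjusted over the list alone (camera adjusted p = 0.473). Of 7 fibroblast markers, Col5a1 rose (0.29) and 6 did not pass, with 1 also adjusted over the list alone (camera adjusted p = 0.324). With either Luc library or Tox4 replicate 1 left out the calls in the neuroectoderm list numbered 2, and with either Luc library left out those in the trophoblast and extraembryonic endoderm list numbered 0. T, Sox1, Fabp7 and Krt19 kept theirs with each library left out, while Epcam lost its call with either Luc library left out (adjusted p up to 0.143) and Bmp4, Cer1 and Col5a1 lost theirs without any 1 of the 4 (up to 0.234, 0.197 and 0.256).

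Among the known partners of Tox4, the 11 genes of the Paf1 complex and the PTW/PP1 phosphatase complex, Ppp1r10 rose (0.75) and 10 did not pass, with 1 also adjusted over the list alone (camera adjusted p = 0.206). Of the other TOX family genes, Tox2 was at 1.36 and 2.06 FPKM with Luc and Tox4 esiRNA (log2 fold change 0.37, limma adjusted p = 0.108) and Tox3 at 1.86 and 2.09 FPKM (0.12, adjusted p = 0.593). Neither passed over all genes, 1 passed as higher adjusted over the list alone, and Tox2 passed in limma-voom on the recovered reads. The family was too small for a list test.

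The p53 targets of the list fixed in advance were higher on balance in the Tox4 libraries. The list does not hold every p53 target, and targets outside it were not counted. Of 16 tested targets, 10 rose, none fell and 6 did not pass, and 14 rose when adjusted over the list alone, with a median log2 fold change of 0.30. Cdkn1a, the p21 cell cycle inhibitor, rose from 54.0 to 85.2 FPKM (0.65, SE 0.04, limma adjusted p = 0.00265). Plk2 rose by 0.62, Eda2r, a tumor necrosis factor receptor family gene, by 0.46 and Trp53inp1 by 0.39. The list passed with a preset correlation (camera adjusted p = 7.65e-12, adjusted p = 0.368 with an estimated correlation). With either Luc library left out the rises numbered 2, Cdkn1a and Plk2, and the list still passed with the preset correlation (adjusted p = 5.59e-11 and 2.72e-12).

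Genes of the integrated stress and unfolded protein response were lower, with 5 of 16 falling, none rising and 11 not past the threshold, and 11 falling when adjusted over the list alone (median -0.20). Trib3 fell by 0.44 on the log2 scale, Chac1 by 0.32, Ddit4 by 0.30 and Asns, the asparagine synthetase gene, by 0.29, and the other was the serine synthesis gene Psat1 (-0.24). These are targets of Atf4 and amino acid shortage, whereas the endoplasmic reticulum chaperone gene Hspa5 was at -0.01; Psat1 and Hspa5 were named after their values were seen. The list passed with a preset correlation (camera adjusted p = 1.01e-06, adjusted p = 0.370 with an estimated correlation), and with either Luc library left out none of its members was past the threshold in limma.

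Interferon response genes were lower too. Of 9 tested members, Cxcl10 (-0.91), Oasl2 (-0.55) and Bst2 (-0.22) fell, none rose and 6 did not pass, and 6 fell when adjusted over the list alone (median -0.23). The list passed with a preset correlation (camera adjusted p = 0.00147, adjusted p = 0.370 with an estimated correlation). It did not pass when genes with low values were kept (adjusted p = 0.0541), and no member was past the limma threshold with either Luc library left out, while Cxcl10 alone was past it without Tox4 replicate 1.

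Mitochondrially encoded transcripts were higher. Of 9 tested genes 6 rose, none fell and 3 did not pass, with 6 also adjusted over the list alone (median 0.25). mt-Cytb rose from 1188 to 1733 FPKM (0.54), mt-Nd4 by 0.39, mt-Nd5 by 0.32 and mt-Nd1 by 0.26 on the log2 scale. The list passed with a preset correlation (camera adjusted p = 4.43e-06, adjusted p = 0.368 with an estimated correlation). None of its members was past the limma threshold with either Luc library left out, and 3 and 4 were without Tox4 replicates 1 and 2.

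Genes of glycolysis and hypoxia were lower, with 4 of 16 falling, none rising and 12 not past the threshold, and 7 falling when adjusted over the list alone (median -0.10). Those that fell were the glucose transporter gene Slc2a1 (629 to 477 FPKM, -0.40), the oxygen sensor gene Egln3 (-0.38), Bnip3 (-0.23) and Vegfa (-0.20), which are targets of the hypoxia-inducible factors rather than glycolytic enzymes. The list passed with a preset correlation (camera adjusted p = 1.60e-05, adjusted p = 0.368 with an estimated correlation). No member was past the limma threshold with either Luc library left out, and 2 were without Tox4 replicate 2.

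Housekeeping and proliferation lists held no calls. None of 16 G1/S genes (camera adjusted p = 0.201), 17 G2/M genes (0.465), 16 cholesterol synthesis genes (0.156), 20 cytosolic ribosomal protein genes (0.559) or 3 replication-dependent histone genes (0.355) passed over all genes with limma, and adjusted over the list alone only 1 histone gene did, as lower. The members with the largest values, none of them past the threshold, included Ccnd3 (0.17), Bub1 (-0.17), Idi1 (0.22), Rpl10 (-0.13) and Hist1h1c (-0.34). Of these 72 genes, 10 had an unadjusted p under 0.05, and in limma-voom on the recovered reads 5 were past the threshold: Ccnd3 as higher and Bub1, Ccnb2, Fdps and Rpl10 as lower. Of 13 immediate early genes, Btg2 (0.34) rose, Klf6 (-0.27) and Jun (-0.22) fell and 10 did not pass; adjusted over the list alone, 6 rose and 5 fell (camera adjusted p = 0.473). Btg2, Klf6 and Jun lost their calls with either Luc library left out (adjusted p up to 0.0783, 0.235 and 0.195), and Klf6 and Jun also with either Tox4 library left out. No gene of the Hox list was tested, since 2 of its 15 members were found in the table and neither had a mean of at least 1 FPKM.

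**Figure D3:**
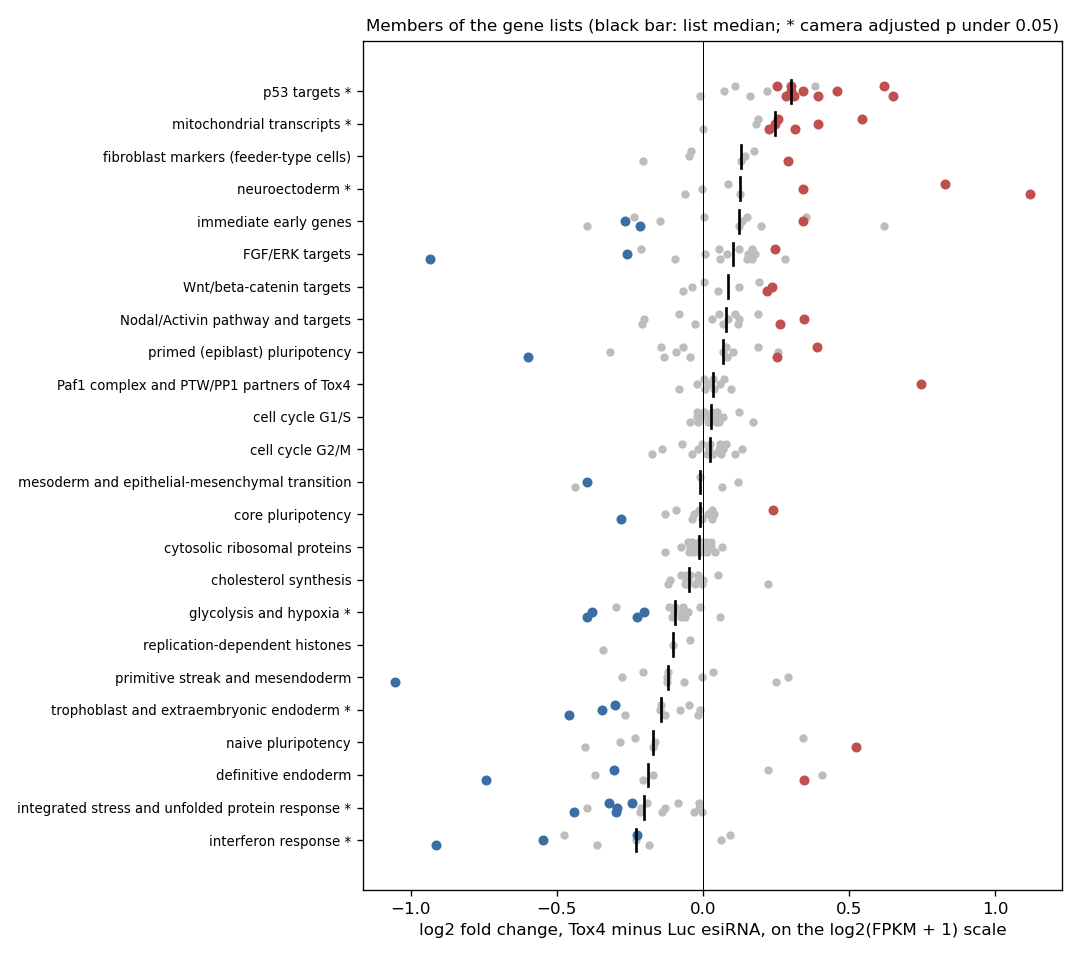
Log2 fold change of Tox4 esiRNA minus Luc esiRNA on the log2(FPKM + 1) scale (horizontal axis) of each tested member of 24 gene lists (vertical axis), with members past the threshold in red (higher) or blue (lower), the others in grey, list medians as black bars and an asterisk at the 7 lists past the camera threshold with a preset correlation. The p53 targets have the highest median (0.30) and the interferon response genes the lowest (-0.23).

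With a preset correlation 7 of 24 lists passed, 3 as higher and 4 as lower, and with an estimated correlation none did. For the neuroectoderm, trophoblast and mitochondrial lists the estimate (-0.15, -0.05 and -0.06) lay under the preset 0.01. Correlation among members therefore does not explain why those lists were lost. The test with an estimated correlation refers each list to 2 residual degrees of freedom, whereas the preset one uses the number of genes. The unadjusted camera p of the p53 list went from 3.19e-13 with the preset correlation to 0.0253 with the estimated one. Failure to pass with an estimated correlation therefore says little about any list. The p53, interferon, integrated stress and glycolysis lists had estimates above 0.01 (0.04, 0.07, 0.22 and 0.03). The fry test, which asks whether a list's genes move on balance in one direction, gave 12 lists past the threshold. With 2 libraries against 2, an exact permutation test of a single gene cannot give a two-sided p below 0.333, so the calls rest on a spread pooled across genes.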

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

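The fits on recovered reads, thinned reads, corrected values and reduced gene sets were chosen after the data had been seen. All 559 genes past the threshold kept their sign in every alternative that tested them. In none of them did the groups overlap. Leaving out a library or changing the pseudocount, filter, intensity trend or block therefore could not change a sign. The number of genes past the threshold moved more. Higher and lower genes numbered 146 and 202 with no filter (15126 genes tested), 365 and 476 with a mean of at least 5 FPKM (9066 tested), 33 and 45 with no intensity trend, 738 and 728 in limma-voom on the recovered reads, 100 and 136 with reads thinned to equal depth, and 43 and 62 with a fold of at least 1.5. Fewer or more genes tested and fewer reads belong to the construction of some of these settings; otherwise the cause was not tested. With each library left out in turn, 27 to 176 genes were higher and 34 to 296 lower; where this left 1 library in a group, it was assumed to vary like the other group. Tox4 passed in every setting that tested it, and with libraries left out the Tox4 log2 fold change lay between -0.92 and -0.86. Pou5f1 passed in none, and with libraries left out the Pou5f1 log2 fold change ran from -0.0059 without Tox4 replicate 2 to 0.066 without Tox4 replicate 1. No list past the threshold changed direction; 7 passed with the preset correlation and 0 with an estimated one, and the interferon list was lost with no filter. Another 4 lists passed in 1 setting each: Nodal and definitive endoderm with a mean of at least 5 FPKM, cholesterol synthesis with the GC and length correction, and immediate early genes without overlapping genes. Of 93 other named genes, none changed sign where it passed the threshold in the main or the alternative fit. Changes of sign among genes that passed in neither fit were not counted. Of 73 named genes past the threshold, Tox4 included, 44 lost the call with no intensity trend, 25 with thinned reads, 15 with no filter, 47 without either Luc library, and 21 and 15 without Tox4 replicates 1 and 2; other settings lost 0 to 7. These losses do not cover the minimum fold of 1.5, which was applied only to the numbers of higher and lower genes. With no intensity trend the losses included Ptn, Cbln1, Rprm, Lrrn2, Dnaic1, Mir293, Mir291b, Fabp3, Atf7, Eda2r and Trp53inp1, Trib3, Chac1, Ddit4 and Asns of the integrated stress list, and Slc2a1, Egln3, Bnip3 and Vegfa of the glycolysis list. With thinned reads they included Mir293, Mir291b, Fabp3, Eda2r, Trib3, Chac1, Bnip3 and Vegfa. Equally numbered libraries shared only a number (correlation of their deviations -0.04), and with it as a block 222 genes were higher and 334 lower. The edgeR test was planned only for files that held counts and was not run. At this depth and with 2 libraries a group, the simulated fit recovered 37.3% of changes of 1.3-fold.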

Other observations

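Chosen only after the results had been seen were the epithelial, MHC class I and hypoxia-inducible factor gene groups, the scan of symbol families, the genes near Tox4, and the tests of GC content and gene length, depth, innate response, scaling, the spread and position of mitochondrial genes, and medium. Several epithelial genes fell in the Tox4 libraries. Of 21 tested genes of epithelial junctions and polarity, from a list of 23 of which 4 also stand in the lists fixed in advance, 10 fell and none rose, with a median log2 fold change of -0.37 (limma). No list test is given for this group or the next 2, because their genes were picked after the values were seen. The E-cadherin gene Cdh1 fell from 29.2 to 16.7 FPKM (-0.77), the epithelial splicing regulator Esrp1 from 5.33 to 2.79 FPKM (-0.74), Cldn7 by 0.70 and Crb3 by 0.61, while the junction scaffold genes Tjp1 (0.02) and Jup (-0.05) did not pass. The median was -0.37 with median-of-ratios scaling and -0.36 with quantile normalization. Falls numbered 2 and 3 without Luc replicates 1 and 2. In a scan of 364 symbol families with at least 5 tested genes, 6 passed with camera at the preset correlation and none with an estimated one. On 2 residual degrees of freedom the latter test could hardly pass over 364 families, so it decides nothing here. Claudins (Cldn, 4 of 7 fell, adjusted p = 0.000543), keratins (Krt, 4 of 6 fell, 0.00204) and annexins (Anxa, 3 of 8 fell, 0.00204) were lower and Sox genes (5 of 9 rose, 0.000543) were higher, as were the mt-Nd genes and the symbol root Trp, whose tested members are all named after Trp53 or Trp73 (adjusted p = 0.978 or more for each with an estimated correlation). Each family's calls numbered 0 to 2 with either Luc library left out and 2 to 4 with either Tox4 library left out.

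Several genes of antigen presentation and several targets of hypoxia-inducible factors fell as well. Of 16 tested genes of the MHC class I pathway 10 fell and none rose (median -0.26). Among them were the immunoproteasome genes Psmb8 (18.9 to 11.4 FPKM, -0.68) and Psmb10 (-0.55), the peptide-loading gene Tapbp (-0.49) and B2m (-0.40), whereas Tap1 was at 0.20 and did not pass. Of 23 tested hypoxia-inducible factor targets, from a list of 24 of which 7 also stand in the lists fixed in advance, 16 fell and none rose (median -0.29). Adm fell from 28.2 to 15.9 FPKM (-0.79), Ankrd37 by 0.55, Ndrg1 by 0.54 and Bhlhe40 by 0.54, while Ldha (-0.06) and Pdk1 (0.06) did not pass. With either Luc library left out, 2 genes of the first group and 4 of the other were past the threshold. Among genes near Tox4 on chromosome 14, Sall2 rose (0.25), while Mettl3 (0.18), Rab2b (-0.09), Supt16 (0.02) and Chd8 (0.11) did not pass.

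The rise of the listed p53 targets was weighed against several technical sources. A bias from GC content or gene length as the whole source is argued against by the median after a correction for both. It was 0.30 with all 16 tested members covered, and the list passed the preset-correlation test. The median in thinned reads was also 0.30, and the list passed there too. This does not decide on a difference in depth, since thinning leaves each gene's expected ratio unchanged. The list's median lay above all of 10000 random lists matched on expression and exon length (percentile 100), the middle 95% of which ran from -0.07 to 0.04. A stronger innate response to double-stranded RNA in the Tox4 wells would raise interferon genes, whose median was -0.23. An off-target effect of the esiRNA, damage or stress in the transfected wells and a response of p53 to the loss of Tox4 stay open as hypotheses, since no other Tox4 esiRNA was analysed here. With an estimated correlation the list did not pass, but on 2 residual degrees of freedom that test could hardly pass.

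The rise of mitochondrial transcripts was not an effect of scaling alone, since the median was at least 0.22 under the other scalings, where the list passed with the preset correlation. The list did not pass camera with an estimated correlation (adjusted p = 0.368), a test on 2 residual degrees of freedom that could hardly pass. Its members lost their calls with either Luc library left out. A higher share of mitochondrial RNA that raises all these transcripts alike is argued against by the spread among 7 members above 50 FPKM: the 95% intervals of 3 excluded the median of 0.25, mt-Nd6 on the low side (-0.00046, -0.09 to 0.09) and mt-Nd4 and mt-Cytb on the high side (0.39 and 0.54). mt-Nd6 is the tested member encoded on the other strand, and the low side rests on it alone. Whether oligo(dT) selection captured mt-Nd6 like the others was not tested. Without mt-Nd6 a spread remained: among members above 50 FPKM, the interval of mt-Cytb (0.45 to 0.64) overlapped only that of mt-Nd4 (0.31 to 0.48). A rise that grows along the heavy-strand transcript is a candidate explanation that the 8 genes cannot settle, with Spearman's rho of 0.52 (exact permutation p = 0.197) and Pearson's r of 0.71 (exact permutation p = 0.0456) across genes, which are not independent, and r of 0.52 without the 2 genes farthest from the median position; mt-Co3 and mt-Atp6 were at only 1.32 and 3.10 FPKM. No biological explanation beyond the esiRNA group was tested.

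The lower integrated stress and glycolysis lists were weighed together. A shift that depends on expression level or gene length is argued against by percentiles of 0 and 0.01 among matched random lists, and GC content or gene length by medians of -0.19 and -0.10 after the correction, with both lists past the preset-correlation test. On the uncorrected values neither list passed camera with an estimated correlation (adjusted p = 0.370 and 0.368), a test on 2 residual degrees of freedom that could hardly pass. Members of both lists lost their calls with either Luc library left out. Fewer cells or less depleted medium in the Tox4 wells could lower hypoxia and amino acid response genes together. The higher of the 2 medians, -0.10, only restates that both lists were lower and decides nothing. This explanation cannot be told apart from an effect of the knockdown on those genes, because the wells differed by esiRNA and cell numbers at harvest were not analysed here.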
